A study of Trypanosoma brucei with 10 samples.

How the data were processed

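Ribosome footprints and mRNA were measured in T. brucei Lister 427 procyclic cells and cultured bloodstream cells. Per the labels' protocols, ribosomes were held in place by a 2 min exposure to cycloheximide (100 µg/ml), at a different temperature in each stage. Part of each lysate was taken for RNA extraction and the rest was digested with RNase I, after which ribosomes were pelleted through sucrose. The label fields on growth medium and molecule give the same text for both stages and assays, so they were not used to tell samples apart. Groups came from the stage and assay in the titles.

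The authors deposited raw counts, whole numbers of reads per coding region, for each library and as a table of the series. Bowtie2 2.2.2, HTSeq and DESeq are named in the submitters' processing notes. The genome build and the handling of reads with several matches are not given in the sources used here, so counts of genes with near-identical copies are uncertain. The 10 columns of the series table equalled the library files, apart from 24 gene identifiers that were written differently. There were 5 identifiers that occurred more than once, and such rows were kept apart. The authors also deposited normalised values, a signal close to the raw count divided by 1 factor per library. Between that table and the raw one the names of the 2 cBF footprint columns were exchanged, and which is right is not given in the sources used here. The raw naming, shared by the library files, was used, and results by cBF pair or replicate number depend on it. Over genes with at least 200 counts, their ratio to the raw counts had a coefficient of variation of 0.670% and 0.637% with the names crossed and 22.8% and 24.1% as named. The other 8 columns stayed at or below 0.780%. These values entered a single alternative, as group means.

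Totals ran from 2509721 to 25036814 counts per library, so 1 read was worth 0.398 CPM in the shallowest library and 0.0399 in the deepest. Replicates of a group differed by 5.99 to 99.6 times the sampling noise (chi-square per degree of freedom), so none was a copy of another. The labels number the replicates without saying that they are separate cultures, so p-values measure the spread between these samples, which may be technical. Bounds set against 0 counts use 3 counts over the group, are the lower of the folds from pooled counts and from the mean CPM of the other stage, and cover counting error only. Binomial intervals are at 95% confidence and cover the same.

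Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr by group, TMM scaling, robust quasi-likelihood fits (glmQLFit and glmQLFTest) and Benjamini-Hochberg adjustment, with calls at an adjusted p of 0.05. Fold changes are cBF minus PCF. The mRNA and footprint comparisons were each fitted on their own 5 libraries. Translational efficiency was tested as the interaction of stage and assay in 1 model of 10 libraries, and the same model gave the ratios within a stage. Scaling over 10 libraries differs from scaling within an assay, so the footprint change minus the mRNA change does not equal the ratio change. SEs were computed from the fold change and its F statistic. Levels are CPM (counts scaled by library total and TMM factor within an assay). Ratios of single pairs used log2 CPM with a prior count of 2.

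Data were simulated with 1 mean per gene and assay, pooled over both stages, with the fitted dispersions and 200 changed genes. The mRNA test (8353 genes run) recovered 97.0% of 4-fold, 22.4% of 2-fold and 1.49% of 1.5-fold changes. The footprint test (8046 genes) recovered 98.5%, 50.7% and 5.97%, and the ratio test (8399 genes) 69.7%, 4.48% and 2.99%. Unchanged genes made up 3.61%, 7.21% and 8.93% of the calls in these tests. With 200 changed genes the adjustment is stricter than in the real comparisons, where more genes were called, so these shares do not give the recovery there. Apart from the 200 changed genes the simulated stages shared their means, so these shares do not cover errors from scaling.

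The descriptions pair each footprint library with an mRNA library, and the protocols take both from 1 lysate. The deviations of paired libraries from their group means had correlations of 0.05, -0.14 and -0.25 in PCF and 0.47 in cBF. The pairing was taken from the descriptions, and a fit with the described pairs as a replicate block gave 4740 calls for translational efficiency beside 4860 without it. Leaving out each library, other scalings, filters and tools (DESeq2 1.42.0, limma 3.58.1) were further alternatives. A fit without multigene families was not run, since it needs product descriptions.

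Gene symbols came from a RefSeq gene table of assembly ASM244v1 (strain TREU927), in which 4432 of the 9164 identifiers (48.4%) had a match and 9 a symbol. The table served for names and for gene order, taken from chromosome and start position, and no distances in bases were used. A set of 30 gene lists by product, such as procyclins, surface glycoproteins and glycolysis, was fixed before the data were examined. By symbol, 1 gene fell into 1 of them, kinetoplast and RNA editing, and the others had 0. The lists match words of product descriptions, which symbols such as PGI, PGKA or KREL2 do not contain, so these counts do not describe what the genes do. No list reached 5 members and no list test was run. The naming rule, also fixed beforehand, asked for the most changed genes with informative products. Where products were lacking it allowed 2 identifiers in each direction, among called genes with no overlap between the stages and a mean of at least 50 counts in the higher group, or in each of the 4 groups for the ratio change. Ratios within a stage needed a mean of at least 50 counts in both assays of that stage and were not limited to called genes. The 9 genes with a symbol were added because they had one, not by their values. Checks of gene length and base composition were void, since under 80% of genes matched the reference table.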

Results

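Trypanosoma brucei, the parasite of African sleeping sickness, lives as the procyclic form (PCF) in the midgut of the tsetse fly and as the bloodstream form in mammals. Ribosome footprints and mRNA were sequenced from strain Lister 427 in both stages, with the bloodstream form taken from culture (cBF). Ribosome profiling sequences the short mRNA pieces that ribosomes shield from nuclease, so a gene's footprint count follows how many ribosomes sit on its coding region. The 10 libraries were 3 of PCF footprints, 3 of PCF mRNA, 2 of cBF footprints and 2 of cBF mRNA. Each footprint library was paired by the labels with an mRNA library of the same stage and number. Reads were counted over 9164 coding regions. Total counts were 5785490, 11446574 and 2509721 for PCF footprint replicates 1 to 3, and 7226490 and 19991775 for cBF footprint replicates 1 and 2. They were 9252275, 17669417 and 25036814 for PCF mRNA replicates 1 to 3, and 13240216 and 12067325 for cBF mRNA replicates 1 and 2. The stated purpose was to learn how gene expression differs between the 2 forms, and the comparisons were of mRNA levels, of footprint levels, of footprints per mRNA, and of the footprint change against the mRNA change. Only 9 genes had a symbol, all on chromosome 1 of the reference assembly, and these are named. The other genes are named by identifier.

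In mRNA, PGI, the glycolytic enzyme glucose-6-phosphate isomerase, was 8.45-fold higher in cBF, at 51.1 ± 9.79 CPM (counts scaled to the library total by TMM) in PCF (SD, n = 3) and 432 ± 30.6 in cBF (SD, n = 2). The log2 change was 3.08 (SE 0.29, adjusted p = 3.03e-05 by the edgeR quasi-likelihood test). The mRNA of beta-coP, a subunit of the COPI coat of Golgi vesicles, was 3.83-fold higher in cBF, from 35.0 ± 16.7 to 135 ± 26.1 (log2 1.94, SE 0.35, edgeR adjusted p = 0.00106). The mRNA of trCOIV, a subunit of the mitochondrial cytochrome oxidase, was 2.64-fold lower in cBF, from 52.0 ± 4.54 to 19.7 ± 1.68 (log2 -1.40, SE 0.24, edgeR adjusted p = 0.000716). The mRNA of TbEAP1 also fell, with a log2 change of -1.05, and so did that of PGKB, the cytosolic isoform of the glycolytic enzyme phosphoglycerate kinase, with -1.08. Each of these 5 calls had its direction in 6 of 6 comparisons of single libraries between the stages. The remaining 4 of the 9 genes did not pass the test: KREPB1 and KREL2 of the mitochondrial RNA editing machinery at 0.31 and -0.36, and the phosphoglycerate kinases PGKC and PGKA at 0.30 and -0.71. Adjusted over the list alone, the number of calls was also 5. KREPB1 and KREL2 also had their direction in 6 of 6 comparisons, so this does not set the calls apart.

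Among genes without a symbol, the mRNAs of Tb927.6.510 and Tb927.10.10260 fell most by the naming rule. Tb927.6.510 stood at 21485 ± 4177 CPM in PCF and 33.6 ± 7.82 in cBF, a log2 change of -9.32. Tb927.10.10260 stood at 15715 ± 5173 and 58.7 ± 32.6, a log2 change of -8.06, which was -8.78 without cBF mRNA replicate 1. Among mRNAs that rose, the rule, which ranks on fitted changes, named Tb927.5.4720 and Tb927.11.17330. Tb927.5.4720 had 0 counts in the 3 PCF mRNA libraries and was at least 86-fold higher in cBF, set against 3 counts over the PCF group. Tb927.11.17330 rose by a log2 change of 8.92, with 0.128 ± 0.162 CPM in PCF and 77.6 ± 54.6 in cBF, where the raw counts were 922 and 3048. Its change was 10.40 without PCF mRNA replicate 2 and 7.93 without cBF mRNA replicate 1.

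Of 8405 genes tested for mRNA, 5534 (65.8%) passed an adjusted p of 0.05, 2855 higher and 2679 lower in cBF. At an absolute log2 change of at least 1 the counts were 2208 and 2195. With all 10 libraries in 1 model, 6055 genes passed, 3668 higher and 2387 lower in cBF. KREPB1 then passed (log2 0.55, edgeR adjusted p = 0.0330). PGKA passed with DESeq2 (log2 -0.78, DESeq2 adjusted p = 0.0204). The 100 most abundant PCF mRNAs held 46.7 ± 2.90% of the counts of the PCF mRNA libraries (SD, n = 3), 10.9 ± 0.0591% of cBF mRNA (n = 2), 8.49 ± 1.54% of PCF footprints (n = 3) and 5.50 ± 0.455% of cBF footprints (n = 2). These genes were chosen in PCF mRNA, which raises their share there. Each library's own 100 most abundant genes held 46.9 ± 2.75% in PCF mRNA, 18.1 ± 1.31% in cBF mRNA, 30.8 ± 1.53% in PCF footprints and 30.1 ± 1.10% in cBF footprints. With the library total as the only scaling, the median log2 change moved by 1.61, the calls became 5985 higher and 868 lower, and trCOIV, TbEAP1 and PGKB turned to 0.21, 0.56 and 0.57, none of which passed. Under that scaling KREL2 (1.26, edgeR adjusted p = 0.00161) and PGKA (0.94, 0.00649) turned upward and passed, and KREPB1 (1.91, 0.000382) and PGKC (1.96, 8.58e-05) passed as well. PGKB also missed the threshold without PCF mRNA replicate 1, PCF mRNA replicate 3 or cBF mRNA replicate 1, at edgeR adjusted p values of 0.0504, 0.0755 and 0.175, and without PCF mRNA replicate 2 KREPB1 (0.0326) and PGKA (0.0141) passed it.

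**Figure D1:**
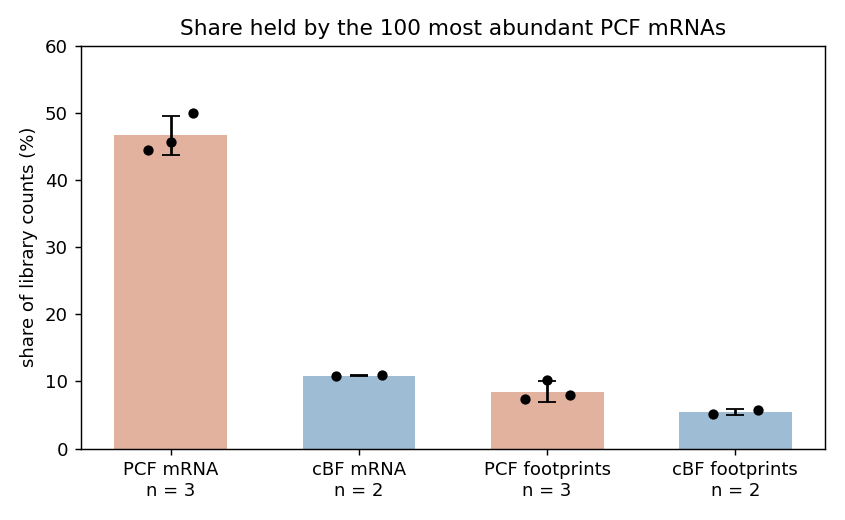
Share of each library's counts, in percent, held by the 100 genes with the most PCF mRNA counts. Bars are group means, error bars SD and points single libraries, and the 3 PCF mRNA libraries lie between 44.4% and 50.0% while the other 7 lie at or below 10.9%.

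In footprints, trCOIV had the widest stage difference of the 9 genes. Its footprints stood at 720 ± 37.7 CPM in PCF (SD, n = 3) and 61.1 ± 6.93 in cBF (SD, n = 2), which was 11.8-fold lower (log2 -3.56, SE 0.22, edgeR quasi-likelihood adjusted p = 3.08e-06). PGI footprints were 6.63-fold higher in cBF, from 275 ± 43.3 to 1820 ± 153 (log2 2.73, SE 0.21, edgeR adjusted p = 9.14e-06). PGKC, the glycosomal phosphoglycerate kinase of the bloodstream form, was 3.29-fold higher, from 378 ± 57.9 to 1245 ± 166 (log2 1.72, SE 0.21, edgeR adjusted p = 0.000143). PGKA footprints rose by 0.72 on the log2 scale and those of KREPB1 fell by 0.78. The footprints of beta-coP, KREL2, PGKB and TbEAP1 did not pass the test, at log2 changes of 0.21, -0.02, 0.20 and -0.45. All 5 calls had their direction in 6 of 6 comparisons of single libraries, and 5 calls were also made when adjusted over the list alone. The uncalled changes of beta-coP and TbEAP1 also had theirs in 6 of 6. The 3 phosphoglycerate kinase genes are neighbours whose coding sequences are similar, so reads may be split between them and their separate values are uncertain.

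Tb927.11.4100 and Tb927.9.7400 had no footprints in the 3 PCF libraries. Against 3 counts over the PCF group, they were at least 331-fold and at least 212-fold higher in cBF, at 60.5 ± 11.7 and 36.4 ± 7.41 CPM. In the other direction, Tb927.3.590 fell from 198 ± 55.7 to 0.222 ± 0.189 (log2 -10.11) and Tb927.5.440 from 904 ± 70.9 to 3.51 ± 0.102 (log2 -8.00). The cBF level of Tb927.3.590 rests on 5 counts, and its change was -10.97 without cBF footprint replicate 1 and -9.04 without replicate 2. The mRNA of Tb927.3.590 stood at 25.8 ± 3.36 CPM in PCF and 5.70 ± 1.59 in cBF, and that of Tb927.5.440 at 83.4 ± 24.8 and 26.6 ± 3.86. For Tb927.11.4100 the mRNA stood at 0.658 ± 0.458 CPM in PCF and 35.6 ± 4.70 in cBF. For Tb927.9.7400 it stood at 0.314 ± 0.158 and 20.3 ± 1.55.

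Of 8072 genes tested for footprints, 4236 (52.5%) passed, 2197 higher and 2039 lower in cBF, of which 1436 and 1350 had an absolute log2 change of at least 1. With the library total as the only scaling the median log2 change moved by 0.34 and the calls were 3311 higher and 1421 lower, and KREPB1 (log2 -0.44, edgeR adjusted p = 0.144) no longer passed while PGKB (0.54, 0.0481) did. With the replicate number as a block, PGKA (log2 0.60, edgeR adjusted p = 0.05004) missed the threshold and TbEAP1 (-0.54, 0.0167) passed it. The block left almost no libraries to measure the spread, so its p-values are uncertain. The footprint call of PGKA was lost in 5 of its 13 alternatives. KREPB1 missed the threshold without cBF footprint replicate 1 (edgeR adjusted p = 0.0636) or replicate 2 (0.123), and PGKA without PCF footprint replicate 1 (0.105), PCF footprint replicate 3 (0.131) or cBF footprint replicate 2 (0.327).

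Translational efficiency, the footprint level relative to the mRNA level of the same gene, fell 5.36-fold in cBF for trCOIV (log2 -2.42, SE 0.37, edgeR quasi-likelihood adjusted p = 8.05e-05). It fell 3.96-fold for beta-coP (log2 -1.99, SE 0.49, edgeR adjusted p = 0.00298), whose mRNA rose between the stages while its footprints did not pass the test. It fell 2.55-fold for KREPB1 (log2 -1.35, SE 0.33, edgeR adjusted p = 0.00248). It rose for PGKA by 1.17 (SE 0.43, edgeR adjusted p = 0.0306) and for PGKC by 1.15 (SE 0.45, edgeR adjusted p = 0.0407). PGI, which rose in both assays, had a ratio change of -0.62 that did not pass, and neither did PGKB at 0.99, TbEAP1 at 0.34 and KREL2 at 0.07. The 5 calls had their direction in 6 of 6 comparisons between single PCF and cBF pairs, and 5 calls were made when adjusted over the list alone. The uncalled changes of TbEAP1 and PGKB also had theirs in 6 of 6.

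**Figure D2:**
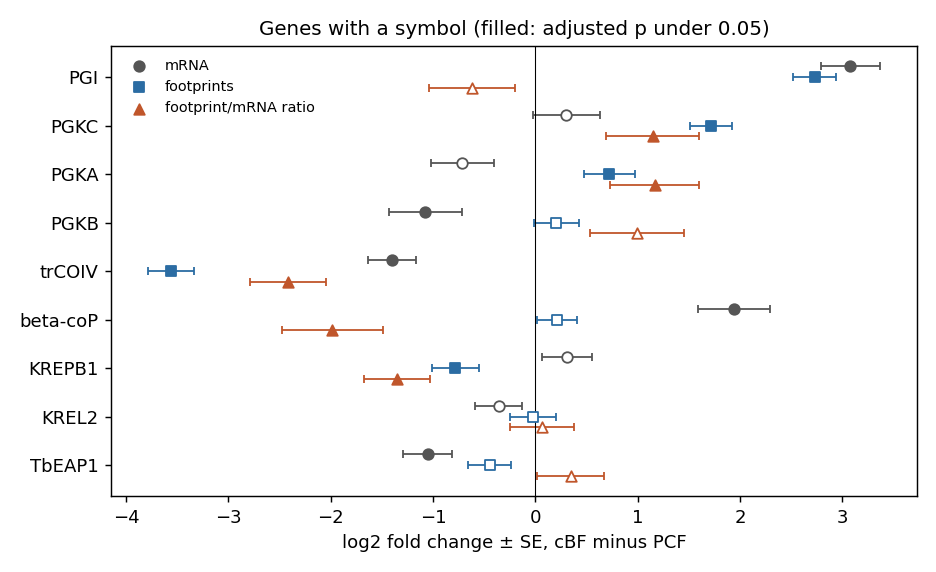
Log2 fold change, cBF minus PCF, of the 9 genes with a symbol in mRNA, footprints and the footprint/mRNA ratio. Error bars are SE, filled symbols passed an adjusted p of 0.05 and open ones did not, and trCOIV lies to the left of 0 in all 3 measures while PGI lies to the right in mRNA and footprints. With the library total as the only scaling, the mRNA points of trCOIV, TbEAP1, KREL2, PGKB and PGKA change side, as do the footprint point of KREL2 and the ratio points of TbEAP1, KREL2 and PGKB.

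Without a symbol, Tb927.6.4580 and Tb927.7.6400 had the largest rises in translational efficiency by the naming rule, both at a log2 change of 4.37 (SE 0.40 and 0.43). The mRNA of Tb927.6.4580 fell from 712 ± 105 to 19.6 ± 6.20 CPM while its footprints went from 50.1 ± 1.72 to 34.5 ± 0.0324. The mRNA of Tb927.7.6400 went from 295 ± 41.8 to 44.9 ± 0.629 and its footprints from 7.36 ± 3.16 to 29.1 ± 1.08. The largest falls were in Tb927.1.275 (log2 -6.73, SE 0.43), with mRNA at 6.89 ± 1.26 and 27.4 ± 10.1 and footprints at 121 ± 12.6 and 5.49 ± 1.27, and in Tb927.5.440 (log2 -6.61, SE 0.48).

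Of 8468 genes tested, 4860 (57.4%) passed, 2254 higher and 2606 lower in cBF, and 4488 had an absolute log2 change of at least 1. The ratio is relative to the average gene of each library, and with the library total as the only scaling its median change moved by -1.01 and the calls became 1046 higher and 4269 lower. PGKA then stood at 0.13 (edgeR adjusted p = 0.802) and PGKC at 0.10 (0.851), while PGI (-1.61, 0.00728) and KREL2 (-0.93, 0.0332) passed. The PCF mRNA libraries enter this contrast, and their 100 most abundant genes held 46.7% of counts against 10.9% in cBF mRNA. Across genes, log2 CPM of PCF footprints correlated with PCF mRNA at r of 0.515 to 0.690 and with cBF mRNA at 0.665 to 0.709, while cBF footprints correlated with cBF mRNA at 0.727 to 0.766 and with PCF mRNA at 0.371 to 0.495. With the described pairs as a replicate block, PGKC (edgeR adjusted p = 0.0705) and PGKA (0.0533) missed the threshold. PGKC also missed it without PCF footprint replicate 1 (0.0921) or 3 (0.0889), cBF footprint replicate 1 (0.0714) or 2 (0.154), PCF mRNA replicate 3 (0.0921), or cBF mRNA replicate 1 (0.191) or 2 (0.0623). PGKA missed it without PCF footprint replicate 1 (0.0806) or 3 (0.0757), cBF footprint replicate 2 (0.195), PCF mRNA replicate 3 (0.0634), or cBF mRNA replicate 1 (0.151) or 2 (0.0542), while PGKB passed without PCF mRNA replicate 2 (0.0145).

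Within PCF, the footprint/mRNA ratio ran from Tb927.10.14550 and Tb927.11.1090 at the top to Tb927.11.4290 and Tb927.11.16430 at the bottom of the genes eligible for naming. Tb927.10.14550 had 8.04 ± 3.19 CPM in mRNA and 1309 ± 82.6 in footprints, a log2 ratio of 7.55, and Tb927.11.1090 had a log2 ratio of 7.22, which was 8.01 without PCF mRNA replicate 2. Tb927.11.4290 had 4997 ± 1134 in mRNA and 38.6 ± 29.4 in footprints, a log2 ratio of -6.80, and Tb927.11.16430 had -6.14. The footprints of Tb927.11.4290 were 21.7, 72.6 and 21.5 CPM in PCF replicates 1 to 3, and its ratio was -7.64 without replicate 2. Of the 9 genes with a symbol, trCOIV had the highest ratio in PCF, 3.99 (SE 0.26), followed by beta-coP at 3.22 and PGI at 2.63. Between the 10th and 90th percentile of genes the log2 ratio spanned 6.28 in PCF, which is 77.8-fold, and the 3 single pairs spanned 6.72, 5.36 and 6.64.

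Within cBF, Tb927.8.910, with 7.79 ± 0.495 CPM in mRNA and 520 ± 156 in footprints, and Tb927.4.1910 (log2 ratio 5.45) were at the top and Tb927.4.3100 (-4.06) and Tb927.10.5900 (-4.03) at the bottom. Without cBF footprint replicate 2 the last 2 stood at -4.76 and -4.55. PGI had a ratio of 2.01, PGKC of 1.89, PGKB of 1.78, trCOIV of 1.57 and PGKA of 1.56, and the lowest of the 9 was KREPB1 at -2.05. The 10th to 90th percentile span was 3.51, which is 11.4-fold, and the single pairs spanned 3.56 and 3.48. Every PCF pair therefore spanned more than every cBF pair, although 3 pairs against 2 allow no exact one-sided p below 0.1. Ratios that differed from the library average at an adjusted p of 0.05 numbered 6620 of 8468 in PCF and 4748 in cBF by the edgeR quasi-likelihood test. With 3 libraries per assay in PCF and 2 in cBF, the test has more power in PCF, so these counts are not directly comparable. Across genes the PCF and cBF ratios, which share no library, had a Pearson r of 0.66 and a Spearman rho of 0.62.

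**Figure D3:**
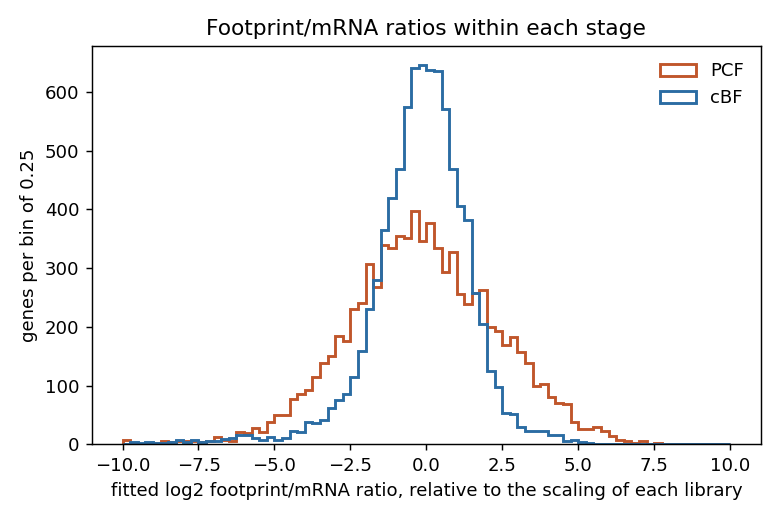
Number of genes by fitted log2 footprint/mRNA ratio in PCF and cBF, over 8468 genes, with ratios beyond 10 in either direction drawn in the end bins. The 10th to 90th percentile span is 6.28 in PCF and 3.51 in cBF.

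The footprint and mRNA changes between the stages were set against each other over the 8056 genes tested in both assays, which share no library. PGI rose and trCOIV fell in both. Over all genes, 1158 rose in both assays and 801 fell in both, where independent lists would give 743 and 656. Opposite calls were made for 848 genes, where independent lists would give 1397. A further 1097 genes rose in mRNA alone, as beta-coP did, and 1424 fell in mRNA alone, as PGKB did. In footprints alone 661 genes rose and 759 fell. That a gene was called in a single assay does not show that its changes differed between the assays, which the ratio test above addresses.

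Across these genes, which are not independent replicates, the footprint and mRNA changes had a Pearson r of 0.49 and a Spearman rho of 0.28. The total least squares slope was 0.91, which reflects mainly the similar SDs of the changes (1.83 for mRNA and 1.74 for footprints). The ordinary least squares slope of the footprint change on the mRNA change was 0.47. Library codes in the table headers place replicate 1 of every group apart from the others. Over 8468 genes, r was 0.37 within replicate 1 and 0.46 within the other libraries. The stage changes measured in these separate sets of libraries had an r of 0.97 for mRNA and 0.94 for footprints.

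**Figure D4:**
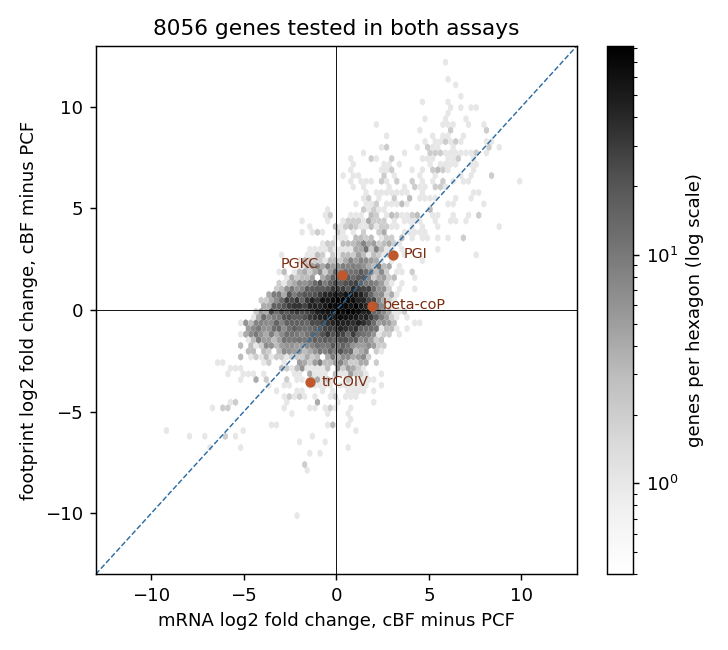
Footprint against mRNA log2 fold change, cBF minus PCF, for 8056 genes, shaded by the number of genes per hexagon on a log scale. The dashed line marks equal change and orange points are 4 genes with a symbol. PGI lies close to the line, trCOIV below it and PGKC above it, and with the library total as the only scaling the mRNA change of trCOIV turns to 0.21.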

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

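The tests of a single aberrant library, of the trend removed in both stages, of correlations between footprint and mRNA libraries, of an axis among the PCF mRNA replicates and of stage-specific translation of the most abundant mRNAs were chosen after the result was seen.

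The interaction test of stage and assay called the footprint/mRNA ratio different between PCF and cBF for 9 of the 13 genes named for that comparison. The 4 without a symbol were chosen as the most changed among called genes, so their calls were fixed by the naming rule. Of the 9 with a symbol, 5 were called, beside 57.4% of all 8468 genes tested. In log2 units, cBF minus PCF, the differences were -2.42 for trCOIV, -1.99 for beta-coP, -1.35 for KREPB1, 1.17 for PGKA and 1.15 for PGKC. For genes without a symbol they were 4.37 for Tb927.6.4580 and for Tb927.7.6400, -6.73 for Tb927.1.275 and -6.61 for Tb927.5.440. The calls of PGKA and PGKC were lost with the described pairs as a replicate block (edgeR adjusted p = 0.0533 and 0.0705), and over their 19 alternatives the adjusted p ran from 0.00338 to 0.802 and from 0.00346 to 0.851. The other 7 calls passed under each of their 19 alternatives. A further limma fit, which subtracted 0.468 of the log2 mRNA level in place of all of it, was not read for named genes.

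The 100 most abundant PCF mRNAs held 44.4% to 50.0% of the counts in PCF mRNA and at most 10.9% in the other 7 libraries. A single aberrant library is argued against: with the 100 genes taken from 1 PCF mRNA library at a time, the lowest share in another PCF mRNA library was 43.8% and the highest in the other groups 11.1%. So is an exchange of stage labels among the mRNA libraries: of the 200 largest called footprint changes, 100 in each direction, 87.0% went the same way in mRNA (95% exact binomial interval 81.5% to 91.3%), and cBF footprints correlated better with cBF than with PCF mRNA, although PCF footprints correlated with cBF mRNA at r of 0.665 to 0.709 and with PCF mRNA at 0.515 to 0.690. An axis of library preparation or culture state that also varies among the PCF mRNA replicates remains a candidate explanation, since PCF mRNA replicate 2 minus replicate 3 had an r of 0.62 across genes with the footprint/mRNA ratio of PCF pair 1, with which it shares no library, of 0.67 with the mRNA change between stages computed without those 2 libraries, of 0.17 with the cBF ratio and of -0.004 with the footprint change, so the mRNA and ratio calls between stages may run partly along it. Stage-specific translation of the most abundant mRNAs cannot be told apart from it, because every PCF mRNA library belongs to 1 stage and the same genes held 10.9% of cBF mRNA.

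The log2 footprint/mRNA ratio spread wider over genes in PCF (10th to 90th percentile span 6.28) than in cBF (3.51). Counting noise at unequal depth is argued against: with every library thinned to 2509721 counts, the gap between the mean pair spans of the stages kept 95.1% of its size over 7867 genes with a mean of at least 100 counts. Removing the trend of the PCF pair 1 ratio on PCF mRNA replicate 2 minus replicate 3 took the span of that pair from 6.72 to 5.16, which left 51.0% of its gap to the mean cBF pair span of 3.52, and 51.8% with the trend also removed from the cBF pairs. The value of 51.0% lies between the bounds set beforehand for this test. The axis among the PCF mRNA replicates may therefore account for part of the wider spread and cannot be told apart from a difference between the stages. A biological difference between the life cycle stages stays open and untested for both patterns.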

How the results depend on the processing

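The fits with PCF mRNA replicate 2 as the only PCF mRNA library and with a term for the library-code batch were chosen after seeing the data. Over all alternatives run, 73 values of the counts, spans and correlation stayed within 1.5 times the count or within the replicate spread and 6 did not. For counts this rule compares the number of calls and not their direction. The library total as the only scaling stayed within it for mRNA, with 6853 calls. Only 3723 of the 5534 main mRNA calls were then made in the same direction. Without 1 library the calls numbered 4214 to 6323 for mRNA, 2916 to 4882 for footprints and 4108 to 5411 for the ratio, and at least 4139, 2870 and 4071 of them were the same genes in the same direction as with all libraries. A stage left with 1 library was assumed to vary like the others. Requiring an absolute log2 change of at least 1 left 2786 of 4236 footprint calls, by construction. The cBF span of 3.51 was 3.36 with a mean of at least 100 counts, where fewer genes enter, and 3.60 to 3.63 without 1 library, more than the difference between the 2 cBF pairs. PCF mRNA replicate 2 alone gave 4558 mRNA calls, 3961 ratio calls, a PCF span of 5.81 and a fold change correlation of 0.56.

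For named genes compared between stages, 538 alternative values kept direction and side of the threshold. With the direction kept, 31 lost the call and 12 gained one. A further 16 changed sign, some of which also lost or gained a call. All of these changes were in the 9 genes with a symbol, while the genes without one had been chosen as the most changed called genes. With the library total as the only scaling, which moved the median of all genes, the mRNA change became 0.56 for TbEAP1, 1.26 for KREL2, 0.21 for trCOIV, 0.57 for PGKB and 0.94 for PGKA, the footprint change of KREL2 became 0.32, and the ratio change became -0.66 for TbEAP1, -0.93 for KREL2 and -0.027 for PGKB. Without 1 library, uncalled changes near 0 took either sign: KREL2 from -0.18 to 0.093 and PGKB from -0.092 to 0.41 in footprints, and KREL2 from -0.14 to 0.18 in the ratio. The cause was not tested. For ratios within a stage, leaving out 1 library of that stage changed no sign and moved the log2 ratio by at most 0.842, for Tb927.11.4290 in PCF. It ended the call of PGKC in PCF in 3 of 6 fits, of PGKB in PCF in 1 of 6 and of beta-coP in cBF in 2 of 4.

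Replicate numbers shared across stages gave deviation correlations of 0.51 and 0.32 in mRNA and 0.21 and 0.40 in footprints, over 2 pairs. With that number as a replicate block, calls were 5715 for mRNA and 4770 for footprints. PGKC mRNA (edgeR adjusted p = 0.0414) and TbEAP1 footprints (0.0167) gained a call and PGKA footprints (0.05004) lost one. Replicate 3 had no cBF library, and these block fits left almost no libraries to measure the spread, so their p-values are uncertain. For PGI mRNA the edgeR adjusted p was 7.49e-26 with the block and 3.03e-05 without it. The paired fit of the ratio (4740 calls) ended the calls of PGKA and PGKC and changed no other call among named genes. The library-code batch term gave 5770, 4275 and 5066 calls. The fits without multigene families, the list tests with an estimated correlation and fry were not run. Depth was not varied in the gene tests, so what it limits there was not tested.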

Other observations

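The 2 tests of neighbouring genes were fixed before their results were seen, and the values for mRNA, for larger distances and for called pairs were computed afterwards.

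Among the 9164 genes, 199 had 0 counts in all 5 footprint libraries, and 1 of them had a mean of at least 100 mRNA counts. In mRNA, 96 genes had 0 counts in all 5 libraries.

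Genes next to each other on the reference assembly ASM244v1 changed together between the stages. Over 3651 pairs of adjacent genes, the footprint log2 changes had an r of 0.30, against a largest absolute r of 0.10 when values were shuffled within chromosomes (2-sided permutation p = 1e-05, the smallest that 100000 permutations can give), so chance order is argued against. Over the 1369 pairs whose mean footprint levels differed at least 4-fold, r was 0.14 (permutation p = 4e-05). This argues against reads shared between tandem copies of similar level as the whole cause. Over the other 2282 pairs r was 0.39, and sharing may add to it there. Reads of a strong gene counted for a weak neighbour could also link pairs of unlike level, so sharing in general is not excluded. Of 1116 adjacent pairs with both genes called, 61.8% moved the same way, where independent directions would give 50.0%. No biological explanation was tested, and genes without a match in the reference table were not placed.

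The correlation fell with distance, to 0.22 for genes 2 places apart, 0.09 for 5, 0.04 for 10 and 0.03 for 20. For mRNA changes it was 0.32 over 3888 adjacent pairs.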
